A study of Escherichia coli with 6 samples.

How the data were processed

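RNA was isolated from 6 samples of bacteria grown in jar fermenters of 5.0 L with 2.0 L of medium at 35 °C and pH 7.0, per the labels' protocols. The medium began with 20 g/L glucose and 80 g/L glycerol, and a feed of 700 g/L glycerol followed. Expression of the introduced enzymes was induced with 0.05 mM IPTG and 50 µM vitamin B12, the latter left out in 1 condition. The labels do not say whether samples of different times came from 1 fermentation or from separate ones. The cells went into an RNA stabilising reagent, total RNA was treated with DNase, and libraries were built with a TruSeq RNA kit, per the labels' protocols. The labels name no step that removes ribosomal RNA and do not say whether the kit kept strand. Overlapping and antisense genes can therefore share reads, and near-identical genes such as gadA and gadB, or introduced and chromosomal gabD, may split them in ways that are not known.

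The authors deposited 1 table per library with an FPKM value for each gene, per the file headers. FPKM are fragments per kilobase of gene, scaled to the size of the library, so each library's values are already divided by a library total that the authors chose. Per the submitters' processing notes CASAVA 1.8.2 and BWA 0.6.2 were used. The genome build, the annotation and the counting step are not given in the sources used here, so coordinates are those printed in the deposited tables, 1-based, on the sequence called Chromosome unless another is named. A table of the whole series gave strand and coding type for 4088 genes, and its number of libraries with a value equalled that in the library tables for 4060 of them. Its 12 columns of values per sample carry names that match no sample label and were not used.

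In all, 4331 features had a value in at least 1 library and 4278 in all 6, including 22 ribosomal RNA and 9 transfer RNA features, 6 on a separate sequence with the introduced genes, 7 insertion elements on a sequence called F, and 15 unnamed features. A feature missing from a library's table was taken as 0. Fixed lists of genes were matched by symbol, with synonyms from a RefSeq table of strain K-12 MG1655 (assembly ASM584v2) used for names only. All but 1 of 559 list genes matched. The list of structural RNAs was matched by the class names in the tables instead of by symbol and was given no percentile.

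Depth was recovered from the low FPKM values, with the gene length that fitted them chosen after seeing the data. With gene length taken as end minus start, 98.1% to 100.0% of the values of genes shorter than 400 nt were whole multiples of 1 read within the rounding of 0.005 FPKM, against 4.2% to 7.3% by chance, and with length 1 nt longer only 43.5% to 81.8% were. The step gave about 25110000, 27680000 and 24080000 reads for SH0012 at 20 h, 30 h and 40 h of the standard run, 23220000 at 30 h and 1200 rpm, 22510000 without vitamin B12 and 26670000 for SH0003, if the smallest step is 1 read. One read in a gene of 1 kb was worth 0.0361 to 0.0444 FPKM. Exact Clopper-Pearson 95% intervals of ratios used these reads. They have no pseudocount, and they cover counting error only, since reads from PCR are not independent molecules.

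Each comparison gave log2(FPKM + 1) of the first condition minus that of the second, for genes at 10 FPKM or more in 1 of the 2 libraries, and counted genes at least 2-fold higher and lower. The pseudocount of 1 understates ratios of low genes. With 1 library per condition there is no p-value and no estimate of the spread between cultures. The fold rule describes these libraries only. The design assumed counts first and named this FPKM route for the case that only normalised values were present. It set no counting interval for this route, so the intervals given here depart from it. They, and the alternatives that use recovered reads, rest on the gene length chosen after seeing the data. The comparisons for agitation, vitamin B12, strain and time at 600 rpm, and the first standard-run comparison, share the SH0012 library at 30 h and 600 rpm, so their ratios share its chance values, and no overlap between them was computed. Likewise agitation and time at 1200 rpm share the library at 30 h and 1200 rpm. Time at 1200 rpm and both standard-run comparisons share the 20 h library, and time at 600 rpm and the second standard-run comparison share the 40 h library. Rescaling divided each library by the median over genes of its ratio to the gene's geometric mean. Levels within a library are given as times the median of its 3836 chromosome genes of at least 300 nt outside ribosomal and transfer RNA.

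Before the data were examined, 28 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The text names the 8 highest and 8 lowest ratios of each single-factor comparison (ribosomal and transfer RNA left out), drawn from up to 4 members with the largest ratios of each list in the outer 2.5% of its random lists on either side, and a fixed set of genes of acid resistance, glycerol use, the lac operon, oxidases, rpoS, yqhD and, for vitamin B12, metE, metH and btuB. The 2 standard-run comparisons name list members and that fixed set. Percentiles came from 10000 random lists of the same size, drawn in 20 bins of mean log2 FPKM. Lists with few members above the band differ mainly by small offsets of low genes.

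The steps were tested on simulated data drawn from the real levels at a single depth close to those estimated, with 4-fold changes planted in 200 genes for agitation, 148 for time at 1200 rpm, 30 for time at 600 rpm, 44 for vitamin B12 and 148 for strain, among 4331. All planted changes were recovered in each of the 5 comparisons, and 0.03% of unchanged genes were called for agitation and 0.0% in the other 4. Changes were planted only in genes at 4 or more times the minimum FPKM, so recovery in low genes was not tested. The whole first library was also given a known log2 shift of -1.0, and calls were made after rescaling. The counts as deposited and the list percentiles were therefore not tested. The simulation had counting error only and no spread between cultures, so it tests the arithmetic and says nothing on how often cultures differ by chance. Alternatives were pseudocounts of 0.1 and 5, no minimum, rescaling, leaving out ribosomal and transfer RNA before scaling, a minimum of 200 recovered reads, and a whole 95% counting interval beyond 2-fold. Chosen after seeing the data were subtraction of the library median and use of the 40 h library in place of the 30 h library at 600 rpm. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.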

Results

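RNA-seq was done on 6 libraries from fed-batch fermentations of Escherichia coli, 5 of strain SH0012, which carries introduced enzymes that make 3-hydroxypropionic acid (3-HP) from glycerol, and 1 of strain SH0003, which the series names as its control strain. The 6 conditions had 1 library each, so no difference below has a replicate check and none was tested between conditions. SH0012 was sampled at 20 h with agitation at 1200 rpm, at 30 h and at 40 h with agitation at 600 rpm, at 30 h with agitation still at 1200 rpm, and at 30 h with 600 rpm but without added vitamin B12. SH0003 was sampled at 30 h with 600 rpm and vitamin B12. Vitamin B12 is the source of the coenzyme of glycerol dehydratase, the first enzyme of the introduced route. The series asks how such strains respond to acid. Of 7 comparisons, 5 change 1 factor each and 2 follow the standard run from 20 h, in which time and agitation change together.

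Ribosomal RNA made up 79.7% of the reads in the SH0012 library at 30 h and 1200 rpm and between 87.1% and 94.2% in the other 5. Estimated depth was close, from about 22510000 reads without vitamin B12 to about 27680000 at 30 h and 600 rpm. The median of 3836 chromosome genes was 19.2 FPKM at 30 h and 1200 rpm, 8.64 FPKM at 20 h, 6.25 FPKM at 30 h and 600 rpm, 3.79 FPKM in SH0003, 2.94 FPKM without vitamin B12 and 2.37 FPKM at 40 h. Around these medians most genes lay in a narrow band. At 30 h and 600 rpm, 94.7% of the genes were within a factor of 2 of the library median and 70 genes were at 3 or more times it. SH0003 had the widest spread, with 70.5% within a factor of 2 and 507 genes at 3 or more times the median. A gene of 1 kb at the library median corresponded to about 446 reads at 30 h and 1200 rpm and to about 57 reads at 40 h, so ratios of low genes were least precise in the 40 h library. Where 1 side of a ratio lay in this band, any part of the band that is not messenger RNA would limit the ratio. Counting intervals do not cover this.

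**Figure D1:**
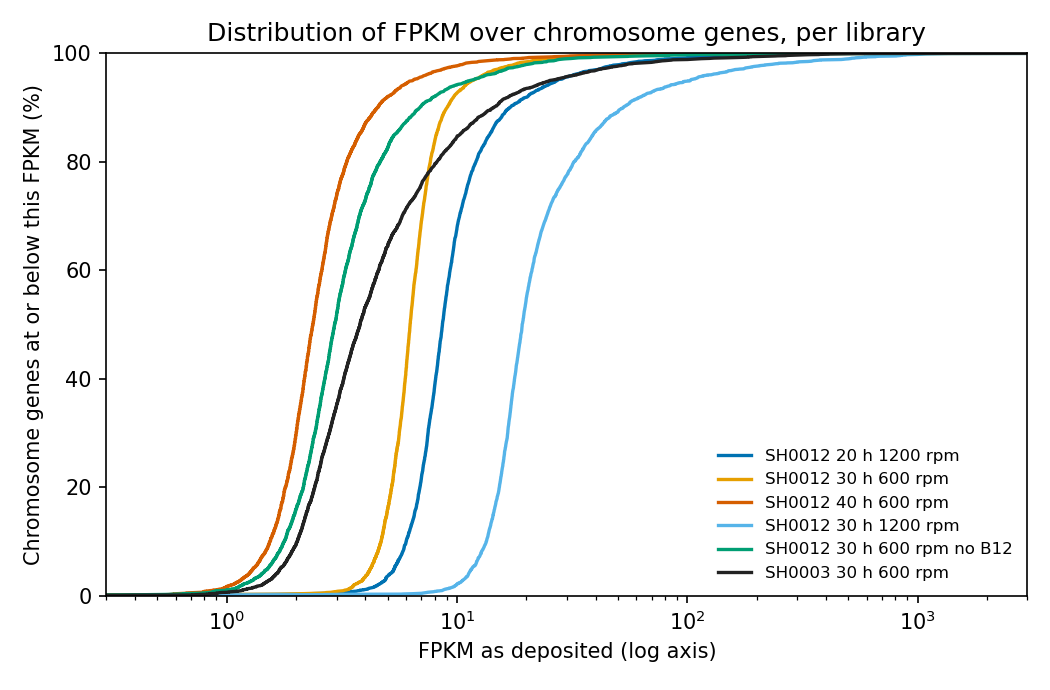
Cumulative share of 3836 chromosome genes (percent, vertical axis) at or below each FPKM (log horizontal axis), 1 line per library. The lines cross 50% at medians from 2.37 FPKM in SH0012 at 40 h to 19.2 FPKM in SH0012 at 30 h and 1200 rpm, and the steepest line, SH0012 at 30 h and 600 rpm, has 94.7% of its genes within a factor of 2 of its median.

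Because the median gene differed between libraries, each comparison has a shift shared by most genes. On the log2 scale the shift was -1.75 for 600 against 1200 rpm at 30 h, 1.2 for 30 h against 20 h at 1200 rpm, -1.38 for 40 h against 30 h at 600 rpm, 1.04 for with against without vitamin B12, 0.65 for SH0012 against SH0003, and -0.55 and -1.93 for the standard run at 30 h and at 40 h against 20 h. Ratios called relative below have this shift removed by rescaling the libraries to the same median ratio. Where leaving out ribosomal and transfer RNA before scaling turned a list median as well, its value is given. FPKM are printed as deposited. For gene lists, the percentile places the list median among 10000 random lists of the same size and mean expression, as a description of the libraries compared. A list is called low or high when it lies in the outer 2.5% on that side. With 27 lists, 1.35 would do so by chance in each comparison if genes were independent, and genes of 1 operon are not.

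The genes of the introduced route were among the most abundant messages in all 6 libraries (chosen after their values were seen). They lie on a separate sequence with 6 features, dhaB (71 to 1734), pduD (1749 to 2312), pduE (2325 to 2789), ddrA (2808 to 4615), an unnamed feature SPCG00000000005 (4615 to 4938) and gabD (5121 to 6560). The names dhaB, pduD and pduE belong to subunits of B12-dependent glycerol or diol dehydratase, ddrA to a subunit of its reactivating factor, and gabD to succinate semialdehyde dehydrogenase, an aldehyde dehydrogenase. In SH0012, dhaB was at 3670 FPKM at 20 h, 2035 FPKM at 30 h and 995 FPKM at 40 h of the standard run, while ddrA was at 1572, 5051 and 3268 FPKM in the same libraries. As times the library median ddrA was highest at 40 h, at 182, 808 and 1379 times, and dhaB did not follow the order of its FPKM, at 425, 326 and 420 times, and its ratio of 40 h to 20 h was 0.04 on the log2 scale after rescaling against -1.88 as deposited. Introduced gabD had its highest FPKM at 20 h, 4110, and was between 1440 and 2341 FPKM in the other 5 libraries, but as times the library median it was highest at 40 h, at 839 against 476 times at 20 h. SH0003 also held the sequence, with 1823 FPKM for dhaB, 7062 FPKM for pduD and 7284 FPKM for ddrA. Without vitamin B12, dhaB was at 860 FPKM, pduD at 1971 FPKM and pduE at 1311 FPKM, the lowest FPKM of the 6 libraries for each. As times the library median these 3 genes were lowest at 30 h and 1200 rpm instead, at 181, 292 and 145 times, against 292, 670 and 446 times without vitamin B12. Chromosomal gabD, which may be similar enough in sequence to share reads, was at no more than 11.7 FPKM. The chromosomal feature lacI, the repressor that IPTG relieves, was at 180 to 852 FPKM, 28.6 to 82.9 times the library median, while lacZ and lacY were at no more than 1.47 times the median in any of the 6 libraries. The labels do not give the genotypes, so it is not known whether a further copy of lacI adds reads to this feature.

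**Figure D2:**
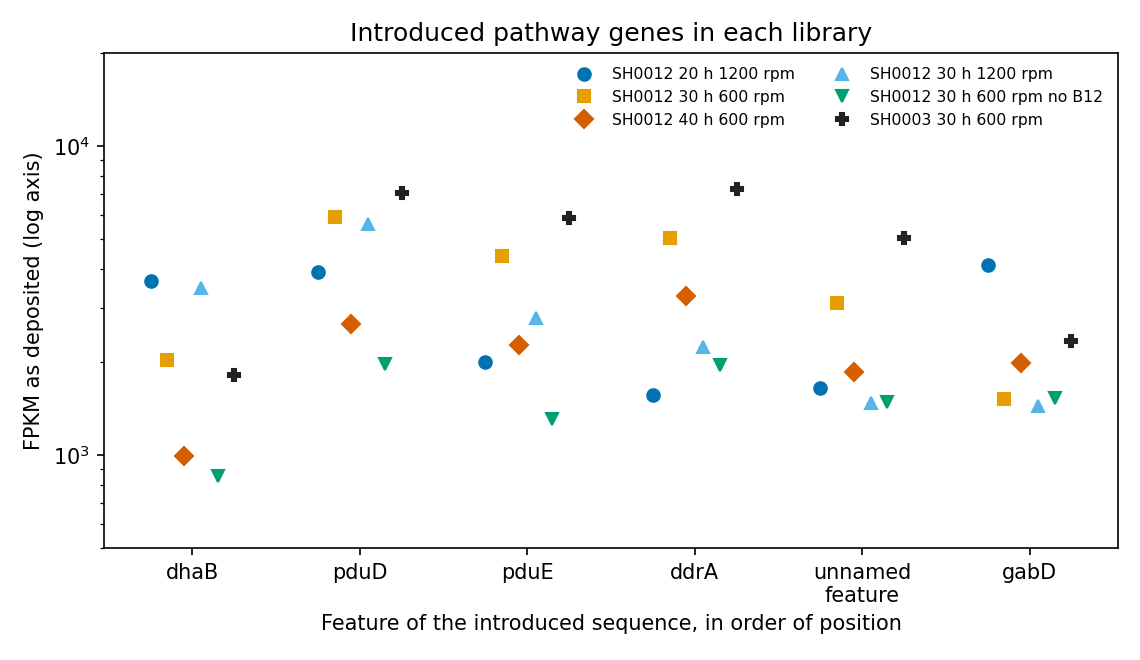
FPKM as deposited (log vertical axis) of the 6 features of the introduced sequence in order of position, 1 point per library. SH0003 has the highest values for pduD, pduE, ddrA and the unnamed feature, up to 7284 FPKM for ddrA, and the library without vitamin B12 the lowest FPKM for dhaB, pduD and pduE, which as times the library median were lowest at 30 h and 1200 rpm.

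At 30 h in SH0012, lower agitation (600 against 1200 rpm) was accompanied by far lower ribosomal protein messages. All 54 genes of the list were at least 2-fold lower at 600 rpm, both as deposited and relative to the shift, with a relative median log2 ratio of -3.51 that lay below all 10000 random lists. The 8 lowest genes of the comparison were rplC, rplD, rpsJ, rplW, rpsN, rpsH, rplO and rpsE, all of the large ribosomal protein clusters between positions 3442127 and 3451292. Large subunit gene rplC was at 8.62 FPKM against 655 FPKM, a log2 ratio of -6.09 as deposited (95% counting interval -6.49 to -6.02) and -4.33 relative, and rpsE was at 13.4 against 849 FPKM. At 600 rpm rplC was at 1.38 times the library median, and metN, atpF and exbD, given below, at 1.17, 0.95 and 0.75 times. These values lie in the band, so if the band is partly background the size of these folds is limited by it. Methionine genes were lower too, with a relative median of -1.96 (percentile 2.0). As times the library median this list was at 1.33 at 600 rpm and 6.88 at 1200 rpm, but at 1.27 in the 20 h library at 1200 rpm. In that list metN, of the methionine importer, was at 7.29 against 301 FPKM, and metB, of cystathionine synthesis, at 8.32 against 206 FPKM. In the cysteine and sulfur list (relative median -0.39, percentile 0.36) cysK, cysteine synthase, was at 20.7 against 1033 FPKM. In the 20 h library at 1200 rpm cysK was at 34.9 FPKM and metN at 16.3 FPKM. ATP synthase genes had a relative median of -1.0 (percentile 0.07), with atpF at 5.92 against 59.2 FPKM. Osmotic stress genes had a relative median of -0.50 (percentile 2.26), with the glycine betaine importer genes proX, at 11.7 against 157 FPKM, and proV, at 23.4 against 270 FPKM. The B12 list (relative median -0.10, percentile 1.68) was low by a small offset of its median, most of its 22 members being near the library median. Its 2 members at the minimum after rescaling were exbD, at 4.68 against 111 FPKM, and exbB, at 7.14 against 122 FPKM, which serve TonB-dependent uptake in general.

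Few genes were higher at 600 rpm. The 8 highest ratios were those of gadX, ddrA, SPCG00000000005, pduE, eamB, htrL, yibA and yibG. Acid resistance regulator gadX (3663009 to 3663833) was at 94.8 against 31.1 FPKM, a log2 ratio of 1.58 as deposited (95% counting interval 1.48 to 1.74) and 3.22 relative. The cysteine exporter gene eamB was at 21.9 against 14.7 FPKM (relative 2.07) and htrL at 89.1 against 61.2 FPKM (relative 2.23). The glutamate-dependent acid resistance list had a median above all 10000 random lists on either scale, at 0.52 relative, 0.35 with ribosomal and transfer RNA left out and -0.99 as deposited. As times the library median this list was at 1.06 at 600 rpm and 0.83 at 1200 rpm, but at 1.1 in the 20 h library at 1200 rpm. Against that 20 h library, the 30 h library at 600 rpm had the list at percentile 72.35 after rescaling. Only gadX and gadW, the latter at 20.1 against 21.4 FPKM and named after its values were seen, were at least 2-fold higher in relative terms, and gadA, gadB, gadC, gadE, hdeA and hdeB, the decarboxylase, antiporter, regulator and acid chaperone genes, were between 0.35 and 0.57 relative. Of the genes always given, cyoA, of the aerobic cytochrome bo oxidase, was at 7.06 against 206 FPKM (relative -2.93) and rpoS, the general stress sigma factor, at 26.9 against 271 FPKM (relative -1.54), while cydA, of cytochrome bd, had a relative ratio of -0.57 and glpF, glpK, lacZ and lacY lay within 0.04 to 0.34. As deposited, 3 genes were at least 2-fold higher and 3786 lower of 4050, and with libraries rescaled 48 were higher and 363 lower of 776.

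At 1200 rpm, the lists high in the 30 h library against the 20 h library of SH0012 included methionine, cysteine, oxidative stress and ribosomal proteins. This 30 h library is also the 1200 rpm side of the agitation comparison. The methionine, cysteine, ribosomal and glutamate-dependent acid resistance results of both comparisons therefore rest on the same single library and are not independent. The 8 highest ratios were those of cysK, sodA, metB, metN, metI, mmuP, metL and rpsE. The cysteine synthase gene cysK (2530431 to 2531402) was at 1033 FPKM at 30 h and 34.9 FPKM at 20 h, a log2 ratio of 4.85 as deposited (95% counting interval 4.79 to 4.99) and 3.63 relative. Manganese superoxide dismutase sodA was at 249 against 9.70 FPKM, metB at 206 against 9.27 FPKM and the S-methylmethionine transporter mmuP at 132 against 7.44 FPKM. The methionine list had a relative median of 2.16, above all 10000 random lists, and all 12 members at the minimum were at least 2-fold higher. The cysteine list had 0.55, also above all of them, with cysJ at 48.3 against 6.86 FPKM. The oxidative stress list had 0.41, again above all, with soxR, soxS and marA each above 40 FPKM at 30 h and below 9 FPKM at 20 h. Ribosomal proteins had 1.37 (percentile 99.95), with 37 of 54 at least 2-fold higher. The envelope stress list was at percentile 97.51 as deposited, with rpoE at 103 against 17.2 FPKM, and was within its random lists after rescaling.

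Lower at 30 h were grcA, a stress-induced spare part of pyruvate formate-lyase (63.6 against 309 FPKM, relative -3.41), lpp, the abundant outer membrane lipoprotein (113 against 407 FPKM, relative -3.00), introduced gabD (relative -2.71) and the small RNA GcvB (35.1 against 87.4 FPKM, relative -2.40). The ratios of slp, glgS, cspC and yobF, next in rank, were between -0.39 and -0.22 as deposited, and the counting intervals of glgS, cspC and yobF included 0. The lists for the tricarboxylic acid (TCA) cycle, acid resistance, branched-chain amino acids and histidine with tryptophan lay below their random lists, with relative medians of -0.39, -0.34, -0.21 and -0.21, and all 4 medians were above 0 as deposited and below 0 with ribosomal and transfer RNA left out. Among them icd, isocitrate dehydrogenase, was at 379 against 151 FPKM (relative 0.12), and gadE at 14.1 against 6.04 FPKM (relative 0.01). As deposited 2711 genes were at least 2-fold higher and 4 lower of 4050, and after rescaling 169 were higher and 30 lower of 792.

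At 600 rpm, the 40 h library had higher levels of a run of neighbouring chromosome genes than the 30 h library. The 8 highest ratios were those of yibW, yibS, 6S RNA, yibG, yibV, yibJ, tdh and yibU, of which the yib genes lie between 3765244 and 3768169. YibW was at 42.0 against 7.74 FPKM (log2 ratio 2.30, 95% counting interval 2.08 to 2.81, relative 3.64), yibJ at 120 against 35.1 FPKM, and tdh, threonine dehydrogenase, at 82.9 against 32.3 FPKM. The regulatory 6S RNA, which binds RNA polymerase, was at 41262 against 10710 FPKM. The 8 lowest were cspE, hfq, grcA, msrB, csrA, glpD, gapC and nlpD. Cold shock family member cspE was at 0.79 against 19.2 FPKM, from about 4 and 111 reads (log2 ratio -3.50 as deposited, -2.69 relative). The RNA chaperone gene hfq was at 1.62 against 16.1 FPKM (relative -1.70), csrA, a regulator of carbon storage, at 2.69 against 16.6 FPKM (relative -1.13) and glpD, aerobic glycerol 3-phosphate dehydrogenase, at 14.3 against 67.1 FPKM (relative -0.84).

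At 40 h, 2 lists lay below their random lists, heat shock (relative median -0.20, percentile 0.13) and ribosomal proteins (relative median -0.25, below all random lists). In them the small heat shock protein gene ibpA was at 6.03 against 25.6 FPKM (relative -0.67), the chaperone gene dnaK at 3.90 against 16.3 FPKM (relative -0.63) and the ribosomal protein gene rpmG at 2.24 against 11.03 FPKM (relative -0.81). No member of either list at the minimum was 2-fold lower in relative terms. Glutamate-dependent acid resistance lay above (0.37 relative, percentile 99.23, but -0.74 as deposited and -0.63 with ribosomal and transfer RNA left out), with gadW at 45.8 against 20.1 FPKM (relative 2.5), mdtF at 10.3 against 8.08 FPKM (relative 1.6) and gadX at 77.5 against 94.8 FPKM (relative 1.08, as deposited -0.29). The structural genes gadA, gadB, gadC and hdeA were between 1.0 and 2.70 FPKM at 40 h, with relative ratios of -0.80 for hdeA and -0.23 to 0.01 for the other 3. For lacI, at 196 against 209 FPKM, the relative ratio was 1.29. As deposited 23 genes were at least 2-fold higher and 183 lower of 364, and the balance turned after rescaling, with 170 higher and 5 lower of 563, but not with ribosomal and transfer RNA left out (32 higher and 2435 lower of 4267). By construction that last scaling lowers most genes at 40 h, where a few small RNAs took 53.4% of the reads outside ribosomal RNA, against 28.3% at 30 h. Neither its counts nor the -0.63 above therefore decide the direction.

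Vitamin B12 was compared at 30 h and 600 rpm in SH0012. The library without it held much more of several regulatory RNAs and of rpoS. CsrB, the small RNA that titrates CsrA, was at 8416 FPKM with and 64777 FPKM without vitamin B12 (relative log2 ratio -3.98, with over without), its partner CsrC at 234 against 2080 FPKM (relative -4.18), and rpoS (2864581 to 2865573) at 26.9 against 182 FPKM (as deposited -2.71, 95% counting interval -2.87 to -2.64, relative -3.74). Vitamin B12 was also present where rpoS was at 271 FPKM (30 h and 1200 rpm), 88.0 FPKM (20 h) and 83.1 FPKM (SH0003). With it, only the 40 h library was below the 26.9 FPKM of this comparison. As times the library median, rpoS was highest without vitamin B12, at 61.9 against 4.22 to 21.9 in the other libraries. CsrB was highest without it on both scales, with SH0003 next at 37317 FPKM. These further libraries also differ in agitation, time or strain. The other genes among the 8 lowest were lpp (17.8 against 270 FPKM), GcvB (11.98 against 149 FPKM), lpxC, of lipid A synthesis (124 against 1274 FPKM), aceK, the isocitrate dehydrogenase kinase (13.0 against 83.1 FPKM) and SgrS, a sugar-phosphate stress small RNA (5.44 against 36.0 FPKM). The direction of the ribosomal protein list depended on the scaling, with a relative median of -1.40, -0.44 as deposited and 0.24 with ribosomal and transfer RNA left out. It lay below all random lists as deposited and rescaled, and after rescaling 40 of the 47 members at the minimum were at least 2-fold lower with vitamin B12. Here rpmI was at 49.2 against 194 FPKM and rplT at 101 against 340 FPKM. The TCA and glyoxylate list had a relative median of -0.89 (percentile 1.1), with aceA, isocitrate lyase, at 23.2 against 62.1 FPKM (relative -2.41), and the aerobic oxidase and NADH dehydrogenase list -0.82 (percentile 0.97), with cydB at 18.0 against 38.1 FPKM (relative -2.06). Both medians were above 0 as deposited, at 0.08 and 0.09, and with ribosomal and transfer RNA left out, at 0.80 and 0.81.

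Higher with vitamin B12 were racR, yigF, pduE, pduD, htrL, ddrA, ybeF and yoeB. The introduced genes pduE (4405 against 1311 FPKM) and pduD (5896 against 1971 FPKM) had relative ratios of 0.71 and 0.54, and racR, a prophage repressor gene, was at 18.8 against 4.76 FPKM (relative 0.87). No gene at the minimum was 2-fold higher after rescaling. More genes could pass that minimum through the library without vitamin B12, which had 265 genes at 3 or more times its median, against 70 with it. The genes for the B12-independent and B12-dependent methionine synthases and the B12 receptor were at the median of both libraries. MetE was at 6.74 FPKM with and 3.54 FPKM without vitamin B12 (relative -0.10), metH at 6.70 and 3.15 FPKM (relative 0.04) and btuB at 6.54 and 2.39 FPKM (relative 0.35). The anaerobic (relative median 0.20), flagellar (0.38) and lac (0.39) lists were high, with no flagellar gene at 10 FPKM. Their members pflB, at 10.6 against 15.0 FPKM (relative -1.45), and lacI, at 209 against 232 FPKM (relative -1.19), went the other way from their lists. The cysteine list was low as deposited (percentile 1.76) and no longer so after rescaling, while the RpoS list (relative median -0.40) reached percentile 2.33 there. As deposited 23 genes were at least 2-fold higher and 48 lower of 398, against 0 and 261 of 694 after rescaling. With ribosomal and transfer RNA left out 3710 were higher and 22 lower of 4262.

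Against the control strain SH0003 at 30 h and 600 rpm, SH0012 had lower ribosomal protein messages. The 8 lowest ratios were those of rplO, rpsE, rpsH, rpmD, rplR, secY, rplF and rpsD, which lie between 3439077 and 3444567. Large subunit gene rplO (3442127 to 3442561) was at 18.3 FPKM in SH0012 and 536 FPKM in SH0003, a log2 ratio of -4.80 as deposited (95% counting interval -5.07 to -4.68) and -5.44 relative. The protein translocase gene secY, which lies among them, was at 24.4 against 451 FPKM and rpsD at 23.0 against 412 FPKM. For the whole list the relative median was -3.22, below all random lists, with 38 of 45 members at the minimum at least 2-fold lower. The acid resistance list was low as well, with a relative median of -0.64 (percentile 1.81), -0.09 as deposited and 0.70 with ribosomal and transfer RNA left out. After rescaling 5 of its 14 members were at least 2-fold lower, among them gadW at 20.1 against 153 FPKM, mdtF at 8.08 against 32.0 FPKM and gadX at 94.8 against 288 FPKM. RpoS was at 26.9 against 83.1 FPKM and cydA at 14.3 against 33.1 FPKM. No gene at the minimum reached 2-fold higher in SH0012 as deposited or rescaled. Its highest ratios, those of exoD, ibpB, ydjF, cspE, ribB, yigF, rppH and yqfA, were between 0.55 and 0.83 as deposited and between -0.03 and 0.27 relative. The minimum of 10 FPKM lay above the 90th percentile of the SH0012 library (9.07 FPKM) and below that of SH0003 (14.5 FPKM), so genes passed it mostly through SH0003. As deposited, with the shared shift of 0.65, 780 were higher and 314 lower of 4309 with no minimum. With a minimum of 200 reads 259 were higher and 259 lower of 1649.

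In SH0012 against SH0003, 4 lists were high. For flagella (relative median 0.65) and lac (0.67) the members other than lacI were near the library median, while lacI went the other way from its list in relative terms (209 against 180 FPKM, relative -0.43). For heat shock and envelope stress the medians were above 0 as deposited, at 0.02 and 0.47, below 0 after rescaling, at -0.59 and -0.09, and above 0 with ribosomal and transfer RNA left out, at 0.85 and 1.36. On the rescaled values their random lists were lower still, at -1.12 and -0.50. Examples are rpoH, the heat shock sigma factor, at 30.5 against 58.0 FPKM (relative -1.54), dnaJ at 15.3 against 25.2 FPKM, ompX at 71.6 against 115 FPKM and skp at 10.7 against 18.5 FPKM, the last 3 with relative ratios of -1.35 to -1.31. As deposited 0 genes were at least 2-fold higher and 296 lower of 710, and 0 and 653 of 1070 after rescaling. With ribosomal and transfer RNA left out 2873 were higher and 123 lower of 4268.

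Along the standard run, the 30 h and 40 h libraries at 600 rpm had lower messages for the TCA cycle, ATP synthase and ribosomal proteins than the 20 h library at 1200 rpm. At 30 h the relative medians were -1.11 for the TCA and glyoxylate list (percentile 0.64), -0.86 for ATP synthase (percentile 0.02) and -2.06 for ribosomal proteins (below all random lists). At 40 h they were -1.04 (percentile 0.52), -0.89 (percentile 0.11) and -2.30 (below all). The isocitrate lyase gene aceA was at 307 FPKM at 20 h, 23.2 FPKM at 30 h and 9.43 FPKM at 40 h, malate synthase aceB at 224, 18.6 and 5.37 FPKM, icd at 151, 11.1 and 4.42 FPKM, and acnB at 137, 17.5 and 7.80 FPKM. Ribosomal protein gene rplC was at 129, 8.62 and 1.72 FPKM and rpsJ at 117, 6.85 and 2.80 FPKM. Among ATP synthase genes atpF was at 25.6, 5.92 and 1.68 FPKM, and cyoA was at 60.2, 7.06 and 1.67 FPKM. Heat shock genes were lower at 40 h than at 20 h (relative median -0.83, percentile 0.94), with dnaK at 3.90 against 80.0 FPKM (relative -2.31) and groS at 1.13 against 21.3 FPKM (relative -1.96).

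In contrast, the regulators gadX and gadW were higher at 40 h than at 20 h, at 77.5 against 26.6 FPKM (relative 3.39) and 45.8 against 9.57 FPKM (relative 3.98), while hdeA was at 1.0 against 11.9 FPKM (relative -1.32) and gadA at 2.08 against 9.93 FPKM (relative -0.28, most of its difference being the shared shift). The list of acid stress regulators had a median of -1.02 as deposited (percentile 98.25) and 0.32 relative, with evgA at 4.26 against 24.7 FPKM (relative -0.56) and phoP at 3.34 against 18.5 FPKM (relative -0.49), and was within its random lists after rescaling. So was the glutamate-dependent acid resistance list (percentile 98.23 as deposited, relative median 0.28). Arginine biosynthesis lay above on both scales (percentile 98.40), at a median of 0.34 relative and -1.24 as deposited, with no member at 10 FPKM as deposited. The B12 list at 30 h was below percentile 2.5 only as deposited (median -0.54). For 30 h against 20 h, 19 genes were at least 2-fold higher and 492 lower of 1393 as deposited, against 49 and 203 of 586 after rescaling. For 40 h against 20 h the counts were 32 and 1237 of 1383 as deposited, and 247 and 231 of 823 after rescaling. With ribosomal and transfer RNA left out they were 65 and 3279 of 4269. By construction that scaling lowers most genes at 40 h, where a few small RNAs took 53.4% of the reads outside ribosomal RNA, against 15.0% at 20 h.

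As levels within each library, ribosomal proteins stood at 21.8 times the library median at 30 h and 1200 rpm, 19.9 times in SH0003, 6.85 times at 20 h, 4.73 times without vitamin B12, and 1.41 and 1.23 times at 30 h and 40 h of the standard run. The methionine list was at 6.88 times the median at 30 h and 1200 rpm, 3.23 times in SH0003 and between 1.16 and 1.33 times in the other 4. Heat shock genes ranged from 1.58 times at 40 h to 5.78 times at 30 h and 1200 rpm, and TCA and glyoxylate genes from 1.32 times at 30 h and 600 rpm to 3.98 times in SH0003. Aerobic oxidases and NADH dehydrogenases ranged from 1.18 to 3.23 times, ATP synthase from 0.95 to 1.98, acid stress regulators from 1.0 to 2.43, envelope stress from 1.21 to 1.94, oxidative stress from 1.05 to 1.64, osmotic stress from 1.02 to 1.58, RpoS general stress from 1.01 to 1.48, arginine biosynthesis from 0.87 to 1.45, glutamate-dependent acid resistance from 0.83 to 1.34, cysteine and sulfur from 0.90 to 1.30 and the lac operon from 0.73 to 1.23. Apart from structural RNAs, the other lists were within 0.63 and 1.12 times the median in all 6 libraries. They were glycerol uptake and dissimilation (0.72 to 1.08 times), aldehyde reductases and dehydrogenases (0.91 to 1.07), the arginine, lysine and ornithine decarboxylase systems (0.91 to 1.12), iron acquisition (0.67 to 0.93), phosphate starvation (0.63 to 0.85), nitrogen starvation (0.63 to 0.89), acetate metabolism (0.65 to 0.81), anaerobic respiration and fermentation (0.74 to 1.01), flagella (0.63 to 0.97), branched-chain amino acids (0.81 to 1.05), histidine with tryptophan (0.87 to 1.07) and the B12 list (0.97 to 1.06). Structural RNAs, the ribosomal, transfer-messenger, 6S and RNase P RNAs, were at 669 times the median at 30 h and 1200 rpm to 8019 times at 40 h. Their median log2 ratio as deposited was between -0.09 and 0.22 in the 7 comparisons. Relative to the shift it was 1.88 for agitation, -1.24 for time at 1200 rpm, 1.47 for time at 600 rpm, -1.13 for vitamin B12, -0.68 for strain, and 0.70 and 2.14 for the standard run at 30 h and 40 h. In the glycerol list glpF and glpK were at 0.75 to 1.15 times the median, and glpD (given here after its values were seen) was at 6.02 times at 40 h, its lowest level, and at 10.7 times at 30 h and 600 rpm.

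**Figure D3:**
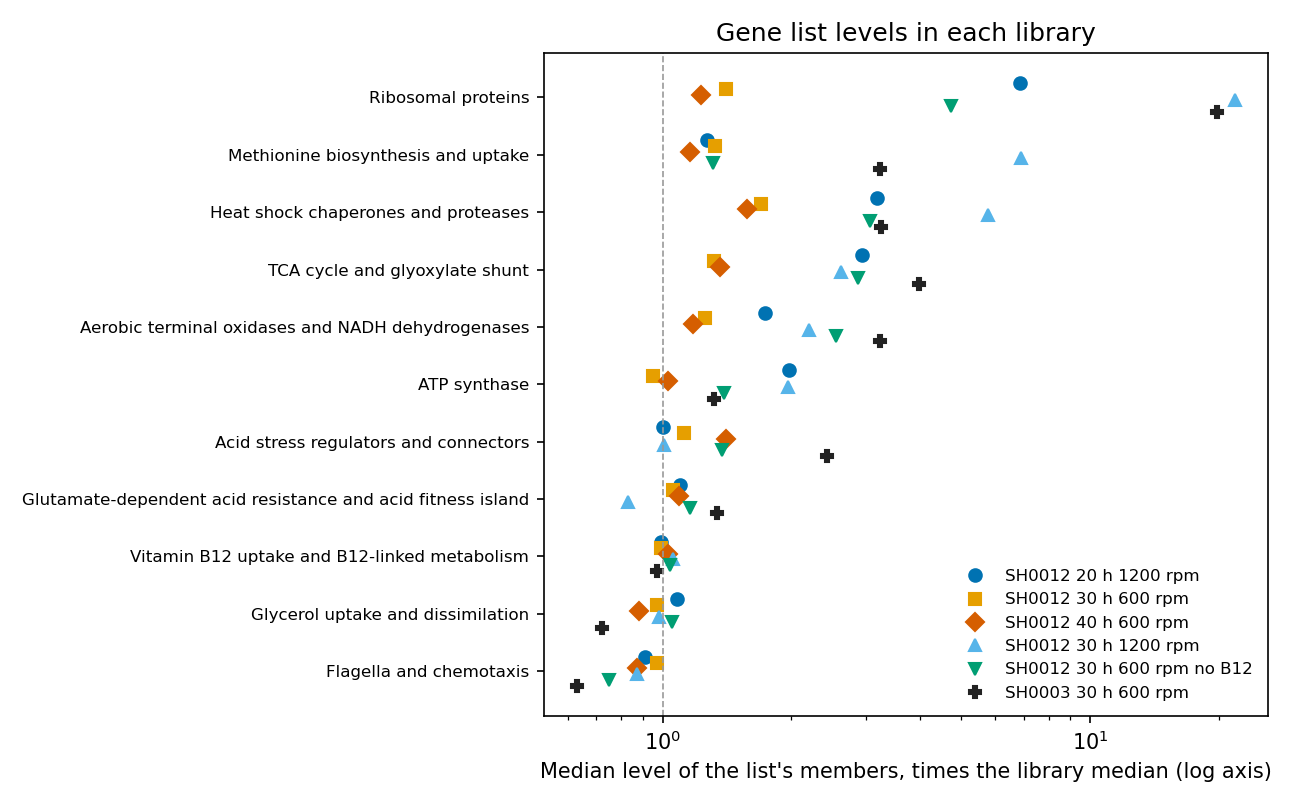
Median level of the members of 11 gene lists, as times the median of chromosome genes of the same library (log horizontal axis), 1 point per library. Ribosomal proteins run from 1.23 times in SH0012 at 40 h to 21.8 times in SH0012 at 30 h and 1200 rpm, while the B12 list stays between 0.97 and 1.06 times in all 6 libraries.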

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

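The 3 alternatives chosen after seeing the data were subtraction of the library median and the 40 h library in place of the 30 h library, as deposited and rescaled. The choice of scale decided most counts, because the median gene was shifted between all pairs of libraries. Counts are given as higher and lower, in the order agitation, time at 1200 rpm, time at 600 rpm, vitamin B12, strain, and the standard run at 30 h and 40 h. The main counts were 3 and 3786, 2711 and 4, 23 and 183, 23 and 48, 0 and 296, 19 and 492, and 32 and 1237. Rescaled to the same median ratio they were 48 and 363, 169 and 30, 170 and 5, 0 and 261, 0 and 653, 49 and 203, and 247 and 231. Higher genes were then 11.7%, 84.9%, 97.1%, 0.0%, 0.0%, 19.4% and 51.7% of those counted, against 0.1%, 99.9%, 11.2%, 32.4%, 0.0%, 3.7% and 2.5%. With ribosomal and transfer RNA left out before scaling they were 46 and 634, 196 and 48, 32 and 2435, 3710 and 22, 2873 and 123, 59 and 469, and 65 and 3279. In the vitamin B12 and strain comparisons this scaling is set by the small RNAs that take 73.9% and 48.6% of the other reads in the second library, and by construction it lowers that library's other genes. In time at 600 rpm and the standard run at 40 h it likewise lowers the other genes of the 40 h library. There the small RNAs take 53.4%, against 28.3% at 30 h and 600 rpm and 15.0% at 20 h. With the library median subtracted they were 55 and 201, 88 and 59, 59 and 29, 46 and 51, 66 and 166, 46 and 135, and 109 and 183. The cause of these moves beyond the scale itself was not tested.

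A pseudocount of 5 gave 1297 higher for time at 1200 rpm, 81 lower for time at 600 rpm, 8 higher for vitamin B12 and 284 lower for the standard run at 30 h. With no minimum, by construction more low genes entered, with 2647 lower for time at 600 rpm, 1356 higher for vitamin B12, 780 higher for strain and 3641 lower for the standard run at 40 h. A minimum of 200 recovered reads admitted long genes of low FPKM, with 996 lower for time at 600 rpm, 435 higher for vitamin B12, 259 higher for strain and 1917 lower for the standard run at 40 h. Whole counting intervals beyond 2-fold left 1796 higher for time at 1200 rpm and 9 higher for vitamin B12. The 40 h library in place of the 30 h library gave 9 higher for agitation, 179 lower for vitamin B12 and 614 lower for strain as deposited, and, rescaled, 241 and 389 for agitation, 83 and 206 for vitamin B12 and 11 higher for strain.

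Rescaling turned the sign of 14 list medians in the outer 2.5% on either side of their random lists. The glutamate-dependent acid resistance list became 0.52 for agitation, -0.34 for time at 1200 rpm, 0.37 for time at 600 rpm and 0.28 for the standard run at 40 h, where the acid stress regulators became 0.32 and arginine biosynthesis 0.34. At 1200 rpm the TCA list became -0.39, branched-chain amino acids -0.21 and histidine with tryptophan -0.21. For vitamin B12 the TCA list became -0.89, the aerobic list -0.82 and the cysteine list -0.26. For strain, heat shock became -0.59 and envelope stress -0.09. Leaving out ribosomal and transfer RNA turned 7 list medians in the outer 2.5%, not all of them among those 14. Glutamate-dependent acid resistance became 0.35 for agitation, -0.46 for time at 1200 rpm and 0.70 for strain, ribosomal proteins became 0.24 for vitamin B12, and at 1200 rpm the TCA list became -0.48, branched-chain amino acids -0.30 and histidine with tryptophan -0.30. The cause was not tested. Among named genes at least 2-fold different and at 3 or more times the median in a library (a bound chosen after seeing the data), the introduced dhaB became 0.34 and pduD 0.23 for time at 600 rpm, and dhaB 0.04, gabD 0.88 and slp 0.30 for the standard run at 40 h. A further 23 named ratios of 2-fold or more, all of genes below 3 times the median, changed sign on rescaling, and 13 when ribosomal and transfer RNA were left out. Of list medians of 2-fold or more within their random lists, 29 and 6 did. No named ratio moved beyond its counting interval with a pseudocount of 0.1, and 214 of 349 did with 5. The ribosomal protein list had the same direction as deposited, rescaled and with ribosomal and transfer RNA left out in 6 of the 7 comparisons, the exception being vitamin B12.

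Alternatives set in advance that need deposited counts (other scalings of counts, prior counts and no count minimum) were not run, since the files hold FPKM. Depth limits genes in the band most at 40 h, where a gene of 1 kb at the median had about 57 reads. No paired analysis was possible because each condition had 1 library.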

Other observations

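Of the tests in this part, only the one on neighbouring genes was chosen before its result was seen.

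Of 15 features without a gene name, which are counted in the comparisons but in no list, the highest value was 13.39 FPKM, for the feature at 2403357 to 2403521 in SH0012 at 30 h and 1200 rpm, 0.70 times that library's median gene. In SH0003 the highest was 4.98 FPKM, 1.31 times its median gene.

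A few small RNAs took a share of the reads outside ribosomal RNA that differed greatly between libraries (named after their values were seen). The transfer-messenger RNA, 6S RNA, CsrB and the RNase P RNA made up 12.6% of those reads at 30 h and 1200 rpm, 15.0% at 20 h, 28.3% at 30 h and 600 rpm, 48.6% in SH0003, 53.4% at 40 h and 73.9% without vitamin B12. The transfer-messenger RNA, which frees stalled ribosomes, was at 15361 FPKM at 20 h, 25472 FPKM at 30 h and 600 rpm, 72772 FPKM in SH0003 and 95627 FPKM without vitamin B12. The 6S RNA was at 5233, 10710 and 41262 FPKM at 20, 30 and 40 h of the standard run and at 42197 FPKM without vitamin B12.

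The regulators gadX and gadW were well above the median in several libraries, together with some but not most members of the acid resistance list. GadX was at 3.08 times the library median at 20 h, 15.2 and 32.7 times at 30 h and 40 h of the standard run, 1.62 times at 30 h and 1200 rpm, 33.8 times without vitamin B12 and 76.0 times in SH0003. In the list of 14 genes, 4 were at 3 or more times the median at 40 h and in SH0003, gadX and gadW included. The others were mdtF, at 4.33 times at 40 h and 8.44 times in SH0003, and slp, at 3.28 and 3.99 times. GadA and gadE stayed between 0.54 and 1.16 times the median in all 6 libraries. The labels do not give the genotypes of SH0012 and SH0003, so a low value below can be low expression or a missing gene. The aldehyde reductase gene yqhD was at 0.02 to 0.04 times the median in all 6 libraries, as ykfC and yqiG were below 0.1 times in each, while its neighbour yqhC was at 0.78 or more. AckA, acetate kinase, was at 0.17 to 0.33 times the median in the 5 SH0012 libraries and at 1.13 times in SH0003, and its neighbour pta at 0.47 to 2.34 times over the 6. The fermentative lactate dehydrogenase gene ldhA was at 52.0 FPKM in SH0003, 13.7 times its median, and at most 3.54 times in SH0012.

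Most genes lay in a narrow band around the library median. Low-level messenger RNA made operon by operon is a candidate explanation, because in 4 of the 6 libraries the levels of band genes correlated more between neighbours on the same strand than between neighbours on opposite strands by over 0.1 (for example Pearson 0.48 against 0.23 in SH0003, across pairs of genes, which are not independent replicates). In SH0012 at 30 h and 40 h of the standard run the gap was not over 0.1 (0.24 and 0.23 against 0.14 in both). The share of ribosomal RNA does not set the height of the band by itself, since the median over the share of other reads differed 4.25-fold between libraries. Those other reads include the few small RNAs, at 12.6% to 73.9% of them, and the part these play in the height was not tested. DNA from replicating cells would be higher near the origin of replication, but the ratio of levels in the 25% of the chromosome around the origin to those in the 25% around the terminus was at most 1.02. DNA from cells that no longer replicate stays open as a part of the band in all 6 libraries, since messenger RNA on top of such DNA could also give the neighbour gap.

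Ribosomal protein genes were low in the SH0012 libraries at 600 rpm with vitamin B12. With the library median subtracted these genes held 2.62% of the remaining coding signal at 30 h and 1.46% at 40 h, against 13.2% at 30 h and 1200 rpm, which is 5.02-fold and 9.01-fold less. This does not settle whether the band of low genes diluted them, because band genes above the median stay in the remaining signal. That signal was 0.57% and 0.41% of all reads, against 8.33% at 30 h and 1200 rpm. Lower agitation alone may account for the low ribosomal protein genes, and with strain and vitamin B12 held the same this cannot be told apart from a difference between 2 single libraries. At 600 rpm the share was 1.22-fold less in SH0003 and 2.87-fold less without vitamin B12, and at 1200 rpm it was 1.56-fold less at 20 h (8.43%, below the 10.8% of SH0003 at 600 rpm). Each of these is a single library. The growth phase at sampling is not known from the labels and stays open.

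The genes yibA, yibJ, yibG, yibW, yibV, tdh, kbl, htrL, rfaL, waaU, rfaZ and rfaY, between 3764360 and 3798988, were picked for their high levels after the values were seen, in SH0003 (median 41.1 times the library median) and in SH0012 at 40 h (15.4 times), at 5.27 times without vitamin B12, at 2.12 times at 30 h and 600 rpm and below 1 at 1200 rpm (0.81 and 0.90 times). A higher copy number of the stretch as a whole is argued against, since the 13 genes between yibI and yibP within it had a median of 0.97 times the library median in both libraries. Those 13 genes lie between the yib genes picked and tdh. Separate gains of the genes on either side therefore stay open. A lower band that lets the same level stand out is argued against in SH0003, where the 15 genes of the stretch at 3 or more times the median at 40 h had a median FPKM as deposited 12.7-fold that at 20 h, the lowest being 3.32-fold. For 40 h, the 18 genes chosen by their level in SH0003 had a median of 2.9-fold that at 20 h with 11 over 1.5-fold and the lowest at 0.24-fold, so a lower band cannot be told apart from a higher level for all of them. A bias by base composition was not tested, since no genome sequence was used, and stays open, as does a shared response to culture conditions, which was not tested.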
